A study of Sus scrofa with 22 samples.

How the data were processed

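The series holds RNA sequencing of pig body tissue from cloned and naturally fertilized (NF) fetuses at day 30 and day 35 and of cloned and fertilized embryos at day 6. Per the labels, fetus libraries were built from total RNA and embryo libraries from cDNA, with NEBNext kits. The authors quantified reads with RSEM 1.2.4 on the pig genome build Sscrofa11.1 (susScr11). The deposited tables, 1 per library, list 65927 RefSeq transcript records with an expected count, the unit of the count column per the file headers. They also give TPM, the length-scaled abundance of RSEM, again per the file headers. The aligner and read filters are not given in the sources used here.

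Records were matched to genes by RefSeq accession without its version, which placed 25305 records (38.4%) in 14399 genes, 616 of them on X and 11 on Y; with the version 4758 (7.2%) matched. Matched records held 66% to 69% of counts in fetus libraries and 79.5% to 85% in embryo libraries, and counts were summed per gene. Genes with every annotated transcript matched were called about as often as others (16% against 14.6% in abnormal against normal fetuses at day 30). Gene counts per library came to 0.41 to 7.65 M in fetuses, with 7985 to 10988 genes detected, and to 5.13 to 17.04 M in embryos, with 6173 to 7300 genes detected.

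Groups followed the labels. Each stage was fitted as a whole, with a mean per group, in edgeR 4.0.16 under R 4.3.3: counts were rounded, filtered with filterByExpr, scaled by TMM and tested with quasi-likelihood F-tests, with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.29 in fetuses and 0.893 in embryos. Abnormal was compared with normal, normal with NF and abnormal with NF at each day, abnormal with normal across both days, and the day 35 effect with the day 30 effect as an interaction. WT was compared with IVF, XIST-KO and WT+Kdm4A with WT, and the remaining embryo pairs as secondary comparisons. Groups, comparisons, tests, gene lists and most alternatives were set before the data were examined. Gene lists with at least 5 tested genes (27 in fetuses, 20 in embryos) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. A further 4 lists were written after the main results were seen and before their own tests. X-linked genes were tested as a set in the same way, with the median log2 fold change of X-linked genes minus that of autosomal genes as the value. The X to autosome ratio was tested by exact permutation of abnormal and normal libraries within days, a test added after the data were seen.

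Genes named had adjusted p under 0.05, an average log2 CPM of at least 1 and, outside the interactions, no overlap of the libraries of the groups. They were taken by size of change, up to 10 per direction in the main comparisons, 3 in the others and 5 in the interactions. Up to 4 changed members per list were taken by size of change alone. Of the genes this rule gives, those whose call held on leaving out each library were preferred, and exceptions are stated. Genes undetected in a group are given as a fold against a floor of 3 counts over the group. Intervals and floors cover counting error only.

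Alternatives were RLE size factors, no filter on low counts, a filter at 1 CPM, DESeq2 1.42.0, limma on log2(TPM + 1), only the compared groups, replicate number as a block, labelled sex as a covariate, each library left out in turn, X without its first 7 Mb, X genes with an average log2 CPM of at least 3, and records matched with their version. Recovery of known changes was tested on simulated data. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. XIST and KDM4A had no matched record and are not analysed here, and neither is the identity of unmatched records. Some further genes are not reported here.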

Results

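RNA was sequenced from 22 pig samples. Body tissue of fetuses at day 30 and day 35 gave 14 libraries in 6 groups, and embryos grown in vitro to day 6 gave 8 libraries in 4 groups. At each fetal day there were 2 libraries of cloned fetuses labelled abnormal, 3 of cloned fetuses labelled normal and 2 of naturally fertilized (NF) fetuses. The embryo groups held 2 libraries each: WT, XIST-KO (XIST, the long non-coding RNA that starts silencing of an X chromosome, knocked out), WT+Kdm4A (Kdm4A is a demethylase of histone H3 lysine 9) and IVF (in vitro fertilized, male and female embryos pooled). Total expected counts ran from 0.59 to 11.54 M per fetus library and from 6.45 to 20.35 M per embryo library. Day 35 abnormal replicate 2 was the shallowest, at 0.59 M, and the next fetus library held 3.46 M. After matching of transcript records to genes, 9913 genes were tested in fetuses and 6960 in embryos. Values are CPM, counts scaled to library size by edgeR, as mean ± SD, and log2 fold changes carry their standard error (SE). No record could be matched to XIST or KDM4A, so their levels are not analysed here. The labels do not say that replicates are separate animals or cultures, so p-values measure the spread between samples.

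Expression of Y-linked genes departed from the sex labels in some fetus libraries. The summed level of 4 Y-linked genes (EIF1AY and 3 genes without a symbol), chosen after their values were seen, was 864 to 1030 CPM in day 30 normal fetuses and 436 to 670 CPM in day 35 normal fetuses. Both day 35 abnormal libraries, labelled male, held 4.07 and 2.46 CPM, where 3 counts correspond to 1.02 and 7.39 CPM. Day 30 NF replicate 1, labelled male, held 0.262 CPM, and replicate 2, labelled female, held 1040 CPM. The day 30 abnormal libraries held 1190 and 600 CPM. The comparison of abnormal with normal fetuses at day 35 therefore also contrasts libraries without and with Y-linked expression.

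**Figure D1:**
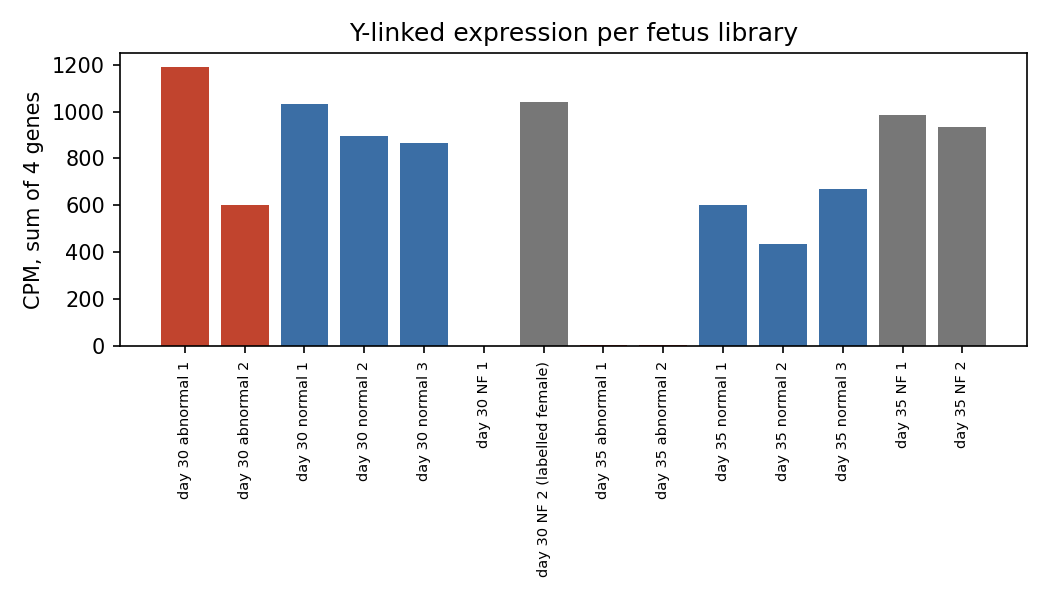
Summed CPM of 4 Y-linked genes in each of the 14 fetus libraries, abnormal in red, normal in blue and NF in grey. Day 30 NF replicate 1 (0.262) and the day 35 abnormal replicates (4.07 and 2.46) lie near 0, and the other libraries lie between 436 and 1190.

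Abnormal and normal cloned fetuses were compared at each day to ask which transcripts differ between clones of unequal development. At day 30, camera at the preset correlation called lists of hypoxia, stress and heart genes higher in abnormal fetuses and lists of muscle, neural and cartilage genes lower, and 0 of 27 lists passed with an estimated correlation. ADM (chromosome 2, 49229223 to 49231521), the low-oxygen-induced vasodilator peptide adrenomedullin, rose from 2.34 ± 1.23 CPM (n = 3) to 77.3 ± 21.7 CPM (n = 2), a log2 fold change of 4.98 ± 0.57 (SE; adjusted p = 0.000555). VEGFA, the vascular growth factor, rose from 62.8 ± 17.9 to 490 ± 78.3 CPM. GATA4 (chromosome 14, 14858470 to 14938156), a transcription factor of heart and foregut, rose from 0.0507 ± 0.0879 to 86.4 ± 26.5 CPM (log2 fold change 9.93 ± 1.04). MYMK, the muscle fusion protein myomaker, fell from 52.6 ± 3.53 to 1.3 ± 0.0201 CPM (log2 fold change -5.31 ± 0.84).

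Of 23 hypoxia and glycolysis genes at day 30, 17 rose and 6 did not pass the test (19 higher when adjusted over the list alone). The list's median log2 fold change was 2.05 (camera adjusted p = 1.73e-11, and 0.346 with estimated correlation). Of 21 heat shock and unfolded protein response genes (the heat shock list), 8 rose (8 adjusted over the list alone), median 0.56 (adjusted p = 0.000158, and 0.0517 with estimated correlation). Among them, ATF3, a stress-induced transcription factor, rose from 8.47 ± 0.814 to 300 ± 85.6 CPM, and PPP1R15A, which relieves translational arrest, rose from 55.7 ± 0.239 to 168 ± 5.98 CPM. Of 16 p53 targets, 7 rose (10 higher and 2 lower adjusted over the list alone), median 0.99 (adjusted p = 3.79e-05, and 0.166 with estimated correlation). ZMAT3, a p53-induced RNA-binding protein, rose from 10.6 ± 2.62 to 90 ± 12.4 CPM. Of 67 cytosolic ribosomal protein genes, 29 rose (46 adjusted over the list alone), median 0.70 (adjusted p = 6.03e-11, and 0.396 with estimated correlation). RPS27L, a ribosomal protein paralog and p53 target, rose from 37.1 ± 5.11 to 90.2 ± 18.2 CPM. On log2(TPM + 1) values the heat shock list had 2 genes higher and a median of 0.24, the p53 list 6 higher, 2 lower and 0.64, and the ribosomal list 12 higher and 0.47.

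Organ markers moved in both directions at day 30. In the cardiac list 6 of 14 genes rose (7 adjusted over the list alone), median 1.53 (adjusted p = 0.000732, and 0.341 with estimated correlation). NKX2-5, a cardiac transcription factor, rose from 0.0507 ± 0.0879 to 11.9 ± 3.18 CPM, and MYL7, the atrial myosin light chain, rose from 6.02 ± 2.22 to 109 ± 40.8 CPM. Of 11 placenta and extraembryonic genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), median 2.0 (adjusted p = 0.00103, and 0.166 with estimated correlation). HAND1, a transcription factor of trophoblast and heart, rose from 0.233 ± 0.228 to 43.3 ± 8.62 CPM. Among 24 leukocyte genes, 11 rose (17 adjusted over the list alone), median 1.75, or 1.67 with undetected genes at their bound (adjusted p = 1.53e-06, and 0.332 with estimated correlation). TYROBP, an adaptor of myeloid receptors, rose from 0.925 ± 0.318 to 8.02 ± 2.87 CPM, a call that ended where records were matched with their version. In the liver list, 8 of 16 genes rose and 1 fell (11 and 1 adjusted over the list alone), median 3.57 (adjusted p = 0.00526, and 0.363 with estimated correlation). The liver call rested on abnormal replicate 2: AFP was 228 ± 321 CPM and AHSG 488 ± 689 CPM in abnormal fetuses, and without that library their log2 fold changes were -0.40 and -2.60 and the list had a median of 1.33 (adjusted p = 0.252). With a library left out the medians ran from 0.68 to 2.15 in the cardiac and 1.10 to 1.99 in the leukocyte list, and on TPM values they were 0.99 and 0.94, with 1.05 for placenta and 1.90 for liver. The calls of AFP and AHSG also ended without any 1 of the normal replicates, with the replicate block and on TPM values.

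Skeletal muscle genes fell in abnormal fetuses at day 30, 11 of 21 (13 adjusted over the list alone), median -1.75 (adjusted p = 5.12e-07, and 0.363 with estimated correlation). In the neural list 7 of 19 genes fell and 1 rose (8 and 2 adjusted over the list alone), median -0.98 (adjusted p = 0.00526, and 0.363 with estimated correlation). INA, the neurofilament subunit internexin, fell from 368 ± 47.5 to 45.4 ± 3.76 CPM, and DCX, a microtubule protein of migrating neurons, fell from 131 ± 22.2 to 23.1 ± 3 CPM. In the cartilage and bone list 7 of 14 genes fell (7 adjusted over the list alone), median -1.06, or -1.28 at the bounds (adjusted p = 0.000681, and 0.346 with estimated correlation). Of 17 fibroblast matrix genes, 3 fell (3 adjusted over the list alone), median -0.29 (adjusted p = 0.031, and 0.396 with estimated correlation). LUM, the collagen-binding proteoglycan lumican, fell from 663 ± 83.7 to 77.5 ± 45.5 CPM, and TWIST2, a mesenchymal transcription factor, fell from 117 ± 18.9 to 17.9 ± 1.81 CPM. The cell cycle list, with 1 gene higher and 1 lower of 18 (1 lower adjusted over the list alone), had a median of -0.85 (adjusted p = 0.0355, and 0.641 with estimated correlation). Without abnormal replicate 2 the muscle median was -3.12, and it was -1.60 without replicate 1. Without replicate 2 the neural, fibroblast matrix and cell cycle lists gave adjusted p of 0.104, 0.0997 and 0.0955. Outside the lists, TAC3, the precursor of neurokinin B, rose from 1.43 ± 1.07 to 146 ± 50.6 CPM, and the Fanconi anemia helicase FANCM and the Wnt receptor FZD9, undetected in abnormal fetuses, were at least 48.8-fold and 36.2-fold lower than in normal fetuses (31.6 ± 3.06 and 23.5 ± 7.14 CPM).

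In total, 1525 genes passed the test at day 30, 885 higher and 640 lower in abnormal fetuses. On TPM values 543 were higher and 1412 lower, 27.8% higher against 58% in the count model, with the median of all genes at -0.27. The count was 584 without abnormal replicate 1, 423 without abnormal replicate 2, 752, 609 and 653 without normal replicates 1, 2 and 3, and 3187 without day 35 abnormal replicate 2, which shares the fit. It was 734 with replicate number as a block, 375 with records matched by version and 3906 with only the compared groups fitted.

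At day 35, camera at the preset correlation called lists of muscle, neural and endothelial genes lower in abnormal fetuses and lists of hypoxia and stress genes higher, and of these the stress list alone passed with an estimated correlation. Fibroblast culture genes, a list added later, rose in 9 of 17 and fell in 1 (median 2.43, camera p = 1.63e-06, and 0.0783 with estimated correlation), after 6 of 17 at day 30 (1.66, p = 0.00341, and 0.241 with estimated correlation). Abnormal replicate 2 had a Spearman correlation of 0.789 with replicate 1 and of 0.908 with day 30 NF replicate 1. MYBPC1 (chromosome 5, 82557975 to 82651237), a myosin-binding protein of skeletal muscle, fell from 155 ± 53.1 CPM (n = 3) to 0.384 ± 0.543 CPM (n = 2), a log2 fold change of -7.81 ± 0.88 (SE; adjusted p = 0.000393). NEFL, the light neurofilament chain, fell from 955 ± 265 to 27.1 ± 0.193 CPM. The endothelial glycoprotein VWF fell from 81.4 ± 4.87 to 2.88 ± 0.264 CPM. TRIB3 (chromosome 17, 34808273 to 34819592), a pseudokinase induced by the unfolded protein response, rose from 0.726 ± 0.167 to 29.4 ± 7.26 CPM (log2 fold change 5.37 ± 0.96). GATA4 rose again, from 0.0761 ± 0.132 to 12.9 ± 6.76 CPM.

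In the skeletal muscle list, 18 of 21 genes fell at day 35, also 18 adjusted over the list alone. Its median log2 fold change was -4.50, or -4.12 with undetected genes at their bound (adjusted p = 3.24e-15, and 0.196 with estimated correlation). TNNC2, a fast muscle troponin, fell from 122 ± 50.7 to 1.54 ± 1.64 CPM, and TNNT3, another, was undetected in abnormal fetuses and at least 79.3-fold lower. Of 19 neural genes, 11 fell (12 adjusted over the list alone), median -2.55, or -2.31 at the bounds (adjusted p = 8.45e-11, and 0.0925 with estimated correlation). INA and NEFM, both neurofilament proteins, fell from 488 ± 160 to 11.5 ± 4.86 CPM and from 706 ± 275 to 47 ± 25.2 CPM. Of 14 endothelial genes, 10 fell (10 adjusted over the list alone), median -3.12 (adjusted p = 2.42e-08, and 0.187 with estimated correlation). Paternally expressed imprinted genes fell too, 9 of 15 with 1 higher (12 and 2 adjusted over the list alone), median -2.73, or -2.24 at the bounds (adjusted p = 7.04e-05, and 0.32 with estimated correlation). DLK1 (chromosome 7, 121565844 to 121577493), a fetal growth ligand, fell from 99.3 ± 42.6 to 0.384 ± 0.543 CPM. Among 26 HOX genes 7 fell and 2 rose (10 and 3 adjusted over the list alone), median -0.92 (adjusted p = 0.00258, and 0.534 with estimated correlation). The posterior genes HOXC12 and HOXC13 fell from 96 ± 37.8 to 0.576 ± 0.814 CPM and from 48.3 ± 17.6 to 2.5 ± 0.279 CPM. Without abnormal replicate 2 the HOX median was -0.49 (adjusted p = 0.797), and on TPM values -2.18. With a library left out the medians ran from -6.55 to -3.15 for muscle, -4.27 to -2.17 for neural and -4.62 to -1.88 for paternally expressed genes, and DLK1 from -11.85 to -6.86.

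The heat shock list rose at day 35, in 16 of 21 genes (17 adjusted over the list alone), median 1.14 (adjusted p = 1.99e-09), a call that held with an estimated correlation (adjusted p = 0.00317). In the hypoxia and glycolysis list 17 of 23 rose (18 adjusted over the list alone), median 2.15 (adjusted p = 1.74e-07, and 0.534 with estimated correlation). ADM rose from 4.79 ± 1.43 to 97.6 ± 65.5 CPM. Of 16 p53 targets, 10 rose and 1 fell (11 and 1 adjusted over the list alone), median 1.18 (adjusted p = 0.000138, and 0.187 with estimated correlation). SESN2, a stress-induced inhibitor of growth signalling, rose from 16.3 ± 1.51 to 179 ± 150 CPM. Of 16 apoptosis genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), median 0.56 (adjusted p = 0.036, and 0.187 with estimated correlation). FAS, a death receptor, rose from 0.056 ± 0.0971 to 8.08 ± 3.83 CPM. Of 16 X-linked genes that escape inactivation in human, 4 rose and 1 fell (6 and 1 adjusted over the list alone), median 0.45 (adjusted p = 0.0365, and 0.534 with estimated correlation). Of these EIF2S3 rose from 167 ± 27.1 to 495 ± 59.6 CPM in libraries low in Y-linked counts. Cytosolic ribosomal protein genes had a median of 0.33, with 8 of 67 higher (3 adjusted over the list alone; camera adjusted p = 0.000628, and 0.843 with estimated correlation), RPS21 rose from 96.5 ± 20.9 to 374 ± 98.2 CPM, and on TPM values the list median was -0.03. On TPM values the hypoxia list had 9 genes higher and a median of 1.39, the heat shock list 10 and 0.85, the apoptosis list 1 higher, 1 lower and 0.21, and the escape list 4 higher, 3 lower and 0.11.

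Blood and kidney markers were mixed at day 35. Of 24 leukocyte genes, 9 fell and 1 rose, as many as adjusted over the list alone, median -1.27, or -1.16 at the bounds (adjusted p = 0.00651, and 0.534 with estimated correlation). C1QB, a complement chain made by macrophages, fell from 52.1 ± 12.5 to 4.03 ± 5.7 CPM (log2 fold change from -10.92 to -2.64 with a library left out). The erythroid list was not called (adjusted p = 0.205), with 4 of 19 genes lower and 3 higher (5 and 3 adjusted over the list alone) and a median of -1.39, or 0.00 at the bounds. HBB, the adult beta globin, fell from 2090 ± 737 to 9.79 ± 13.8 CPM, and SPTB, the red cell spectrin, fell from 80.9 ± 30.9 to 3.85 ± 2.19 CPM. The embryonic globins HBE1 and HBZ were higher, at 671 ± 948 and 436 ± 617 CPM against 16.1 ± 11.7 and 12 ± 5.92 CPM, in abnormal replicate 1 alone: without it their log2 fold changes were -9.23 and -8.79 (adjusted p = 0.413 and 0.473), and both calls ended without normal replicate 1 and on TPM values. Kidney genes did not pass as a list (adjusted p = 0.13), and PAX2, a transcription factor of the kidney tubule, was undetected in abnormal fetuses and at least 59.1-fold lower.

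The day 35 comparison passed 2301 genes, 1086 higher and 1215 lower. On TPM values 497 were higher and 2382 lower, 17.3% higher against 47.2%, with the median of all genes at -0.32. The count was 3645 without abnormal replicate 2 and 1418 without normal replicate 1, 609 with version matching and 297 with only the compared groups fitted, where the calls of C1QB, HBE1 and HBZ ended. Without abnormal replicate 1, the lists for hypoxia (median 0.25, adjusted p = 0.399), p53 targets (0.14, 0.163), apoptosis (0.38, 0.0757), leukocytes (-2.40, 0.282), escape genes (0.03, 0.138) and ribosomal proteins (-0.09, 0.262) lost their calls. The escape list also lost its call without abnormal replicate 2 (adjusted p = 0.13), without normal replicates 1 and 3 (0.0942 and 0.112) and with the replicate block (0.0559), and the apoptosis list without abnormal replicate 2 (0.306).

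**Figure D2:**
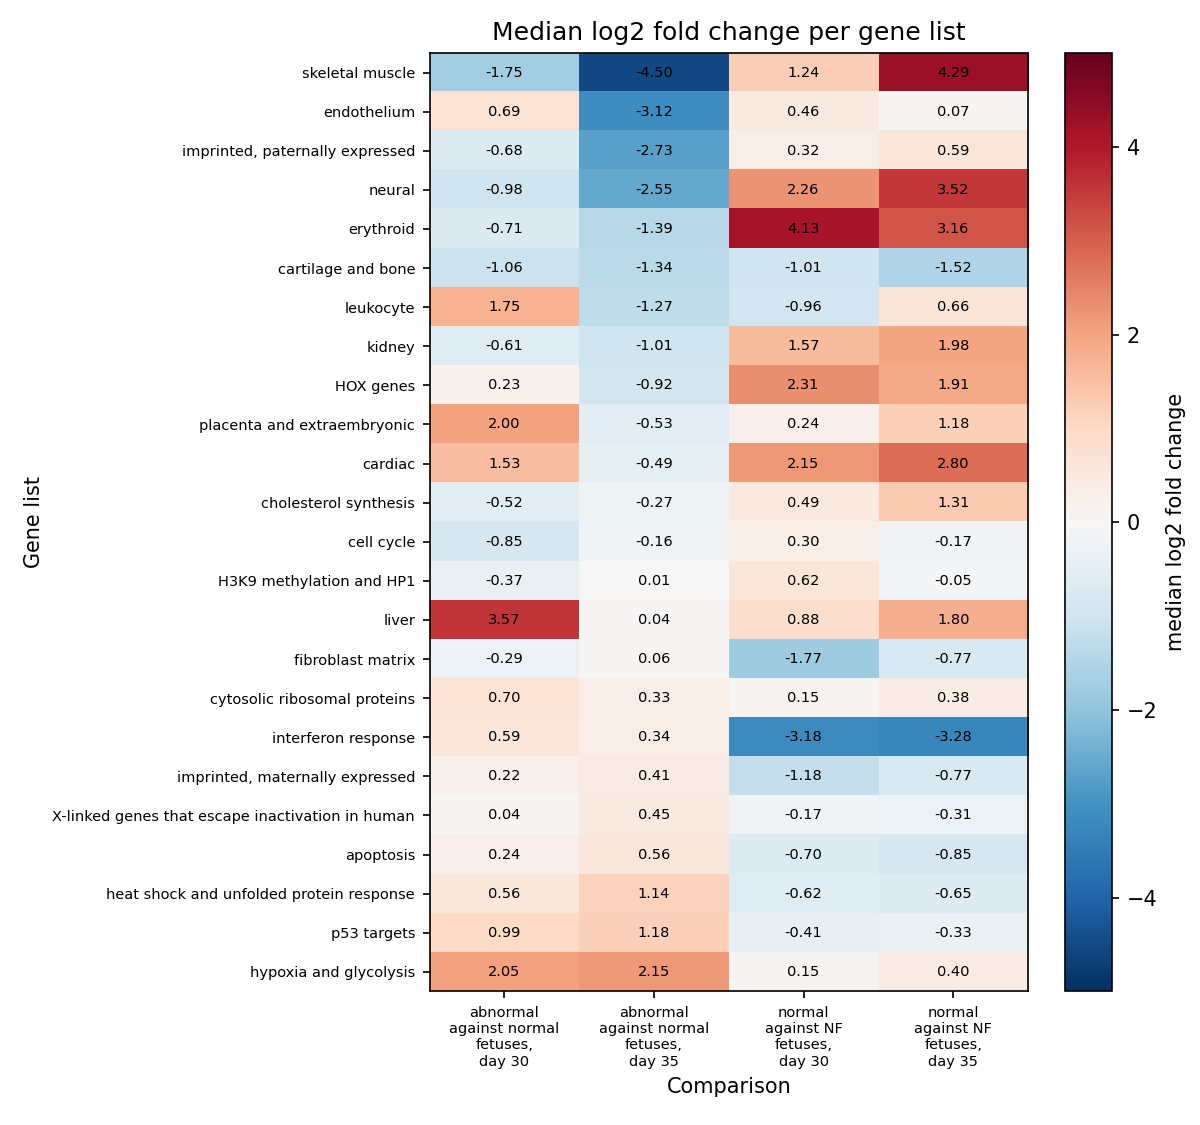
Median log2 fold change of each gene list called in at least 1 of the 4 comparisons shown in columns. The skeletal muscle median was -4.50 in abnormal against normal and 4.29 in normal against NF fetuses at day 35.

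Across both days, 3073 genes passed in abnormal (n = 4) against normal (n = 6) fetuses, 1511 higher and 1562 lower (1604 and 1456 with RLE size factors, 52.4% higher against 49.2%, and 710 and 2954 on TPM values, 19.4%, with the median of all genes at -0.30). TTR, the thyroid hormone carrier transthyretin, was undetected in normal fetuses and at least 119-fold higher in abnormal fetuses (11.3 ± 5.59 CPM). GATA4 rose from 0.0634 ± 0.101 to 49.7 ± 45.3 CPM. FOSL1, a component of the AP-1 transcription factor, rose from 0.142 ± 0.12 to 48.3 ± 72.2 CPM. FANCM and RAB3GAP1, a regulator of vesicle traffic, were undetected in abnormal fetuses and at least 54-fold and 29.9-fold lower. The heat shock list rose in 16 of 21 genes (17 adjusted over the list alone), median 0.79 (adjusted p = 2.61e-09, and 0.00349 with estimated correlation), on TPM values in 11 with a median of 0.50. Camera called 9 lists across both days, and 1, this list, with an estimated correlation; the endothelial list gave adjusted p = 0.0659 without day 35 abnormal replicate 1. Calls of the days overlapped in 337 genes higher at both (97 expected if independent) and 316 lower at both (78.4 expected), with 42 in opposite directions (178.6 expected) and a correlation across genes of 0.41, where genes are not independent replicates. The difference between the days was tested as an interaction: 397 genes passed, 130 with a higher and 267 with a lower effect at day 35 (DESeq2 942).

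The interaction count was 2892 without day 35 abnormal replicate 1, 1195 without day 35 abnormal replicate 2, 170 and 123 without day 30 abnormal replicates 1 and 2, and from 113 to 211 without a normal library. Of 24 leukocyte genes, 11 were called higher at day 30, and 9 lower and 1 higher at day 35. The list's median was 1.75 at day 30, -1.27 at day 35 and -3.0 for the interaction (camera adjusted p = 2.87e-12, and 0.178 with estimated correlation). The interaction medians of endothelial and cardiac genes were larger, at -3.62 and -3.59 (adjusted p = 2.18e-13 and 9.27e-05, and 0.178 and 0.215 with estimated correlation). On TPM values the interaction medians were -1.87 for leukocyte, -3.10 for endothelial and -2.52 for cardiac genes, and for skeletal muscle genes -1.39 against -2.32.

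Normal clones were compared with NF fetuses to describe clones without overt defects, but sampled tissue may differ. At day 30, camera at the preset correlation called lists of red cell, neural, kidney, heart and muscle genes higher in the clones and lists of interferon and fibroblast matrix genes lower, and 0 of 27 lists passed with an estimated correlation. The added fibroblast culture list was lower too, in 11 of 17 genes at day 30 and 10 of 17 at day 35, with 1 gene higher at each day (medians -2.34 and -2.14). HBZ (chromosome 3, 41490758 to 41492883) and HBE1, the embryonic globins, rose from 0.229 ± 0.323 CPM and 0.602 ± 0.658 CPM (n = 2) to 718 ± 290 and 1270 ± 506 CPM (n = 3), log2 fold changes of 11.52 ± 2.08 and 11.02 ± 2.07 (SE; adjusted p = 0.00275 and 0.00325). INA rose from 7.57 ± 1.65 to 368 ± 47.5 CPM. RSAD2 (chromosome 3, 128880853 to 128897809), an antiviral protein induced by interferon, fell from 13.3 ± 11.7 to 0.0615 ± 0.107 CPM. TNC, the matrix protein tenascin C, fell from 5070 ± 305 to 455 ± 57.9 CPM.

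Of 19 erythroid genes, 14 rose at day 30 (14 adjusted over the list alone), median 4.13 (adjusted p = 1.62e-07, and 0.168 with estimated correlation). SLC4A1, the red cell anion exchanger, was undetected in NF fetuses and at least 130-fold higher in normal clones (28.1 ± 8.97 CPM). In the neural list 13 of 19 rose (16 adjusted over the list alone), median 2.26 (adjusted p = 3.83e-10, and 0.0642 with estimated correlation), among them ELAVL3, a neuronal RNA-binding protein, from 1.9 ± 1.18 to 68.2 ± 7.8 CPM. Among 26 HOX genes 19 rose (20 adjusted over the list alone), median 2.31, or 2.17 at the bounds (adjusted p = 2.27e-07, and 0.266 with estimated correlation). HOXC12 rose from 1.24 ± 1.53 to 50.2 ± 7.52 CPM. Kidney genes rose in 6 of 10 (6 adjusted over the list alone), median 1.57 (adjusted p = 0.000167, and 0.0642 with estimated correlation). PAX2 rose from 1.01 ± 0.0792 to 17.9 ± 4.03 CPM, and LHX1 (chromosome 12, 38450708 to 38457583), also a factor of early kidney, was at least 134-fold higher. Cardiac genes rose in 8 of 14 (8 adjusted over the list alone), median 2.15 (adjusted p = 0.0045, and 0.266 with estimated correlation), with MYH7, the slow myosin heavy chain, going from 1.54 ± 1.1 to 70.4 ± 17.2 CPM. Of 21 skeletal muscle genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), median 1.24 (adjusted p = 0.0045, and 0.647 with estimated correlation). MYBPC1 rose from 1.09 ± 0.187 to 57.4 ± 20.3 CPM. In the list of H3K9 methylation and HP1 factors 3 of 10 rose (3 adjusted over the list alone), median 0.62 (adjusted p = 0.022, and 0.266 with estimated correlation). CBX1, a heterochromatin protein, rose from 232 ± 29.5 to 534 ± 20.4 CPM. On TPM values the medians were 1.73 for erythroid, 1.03 for kidney and 0.78 for muscle genes, and at day 35 0.79 for erythroid and 1.01 for kidney genes.

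Interferon response genes fell in 17 of 21 at day 30 (19 adjusted over the list alone), median -3.18 (adjusted p = 9.5e-08, and 0.295 with estimated correlation). MX1, an antiviral GTPase, fell from 205 ± 241 to 5.73 ± 1.12 CPM. With a library left out the interferon median ran from -3.88 without NF replicate 1 to -1.73 without NF replicate 2, and MX1 from -6.01 to -2.56. Of 17 fibroblast matrix genes 12 fell and 1 rose, as many as adjusted over the list alone, median -1.77 (adjusted p = 2.15e-06, and 0.154 with estimated correlation). LOX, the collagen cross-linking oxidase, fell from 404 ± 137 to 36.9 ± 3.01 CPM. In the cartilage and bone list 5 of 14 fell (5 adjusted over the list alone), median -1.01 (adjusted p = 0.0443, and 0.508 with estimated correlation). COMP, a cartilage matrix protein, fell from 65.8 ± 1.16 to 0.756 ± 0.84 CPM. Leukocyte genes fell in 8 of 24 (8 lower and 1 higher adjusted over the list alone), median -0.96 (adjusted p = 0.0045, and 0.426 with estimated correlation). The chemokine CCL2 fell from 280 ± 285 to 0.944 ± 0.174 CPM. In the heat shock list 10 of 21 genes fell (10 adjusted over the list alone), median -0.62 (adjusted p = 0.0032, and 0.0642 with estimated correlation). Within it ATF4, the translation-controlled stress factor, fell from 998 ± 336 to 328 ± 35.5 CPM, and TRIB3 from 31.9 ± 37.2 to 0.718 ± 0.663 CPM. Maternally expressed imprinted genes fell in 4 of 8 with 2 higher (5 and 2 adjusted over the list alone), median -1.18 (adjusted p = 0.0443, and 0.196 with estimated correlation). TFPI2, a protease inhibitor, fell from 117 ± 61.8 to 7.76 ± 1.3 CPM, and IGF2R, the receptor that clears IGF2, from 840 ± 161 to 183 ± 12.6 CPM. Outside the lists, the collagenase MMP1 fell from 85.1 ± 20.5 to 0.0507 ± 0.0879 CPM, FOSL1 from 96.8 ± 37.1 to 0.163 ± 0.153 CPM, and the cytokine IL6 was at least 47.7-fold lower. Without normal replicate 1 and without NF replicate 1 the cartilage list gave adjusted p of 0.0543 and 0.0836, without normal replicate 2 the maternally expressed list 0.0628, and without NF replicate 1 the H3K9 list 0.086.

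The day 30 comparison of normal clones with NF fetuses passed 2905 genes, 1386 higher and 1519 lower (1224 and 1006 on TPM values, 54.9% higher against 47.7%, and 1521 and 1355 with RLE size factors). The count was 1875, 1857 and 1888 without normal replicates 1, 2 and 3, 1287 without NF replicate 2 and 4453 without day 35 abnormal replicate 2. It was 731 with version matching and 1295 with the labelled sex as a covariate, which sets aside the library labelled female, NF replicate 2, and does not adjust for Y-linked expression.

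At day 35 the organ lists were again called higher in normal clones than in NF fetuses and the interferon and matrix lists lower, and again 0 of 27 lists passed with an estimated correlation (adjusted p at least 0.0988). Genes called higher at both days numbered 12 in the neural, 9 in the muscle, 8 in the cardiac, 5 in the kidney and 4 in the erythroid list. Those called lower at both days numbered 16 in the interferon and 8 in the fibroblast matrix list. INA (chromosome 14, 114227998 to 114240566) rose from 3.43 ± 3.13 CPM (n = 2) to 488 ± 160 CPM (n = 3), a log2 fold change of 7.13 ± 0.55 (SE; adjusted p = 4.65e-05). ACTA1, skeletal alpha actin, rose from 1.98 ± 0.826 to 280 ± 150 CPM, and MYH7 (chromosome 7, 75650841 to 75672908) rose from 0.952 ± 0.137 to 217 ± 123 CPM. TNC fell from 6720 ± 2230 to 435 ± 26 CPM, and RSAD2 fell from 12.2 ± 1.65 to 0.0658 ± 0.114 CPM.

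In the neural list 14 of 19 genes rose at day 35 (17 adjusted over the list alone), median 3.52 (adjusted p = 3.18e-10). FABP7, a fatty acid carrier of radial glia, rose from 1.47 ± 0.144 to 287 ± 129 CPM, and the axonal adhesion molecule L1CAM was at least 614-fold higher (159 ± 66.4 CPM). Of 21 skeletal muscle genes 15 rose and 1 fell (15 and 2 adjusted over the list alone), median 4.29 (adjusted p = 9.6e-07), with the myosin light chain MYL1 going from 1.47 ± 0.589 to 219 ± 50 CPM. Cardiac genes rose in 8 of 14 (8 adjusted over the list alone), median 2.80, or 2.48 at the bounds (adjusted p = 0.00227). The ventricular light chain MYL2 rose from 0.954 ± 0.381 to 137 ± 67.3 CPM. HOX genes rose in 16 of 26 (16 adjusted over the list alone), median 1.91, or 1.97 at the bounds (adjusted p = 5.48e-05). HOXC12 rose from 0.0855 ± 0.121 to 96 ± 37.8 CPM, and HOXB13 was at least 51.2-fold higher. Kidney genes rose in 5 of 10 (6 adjusted over the list alone), median 1.98 (adjusted p = 0.00104), and 1.67 to 3.36 with a library left out. LHX1 rose from 0.258 ± 0.118 to 54.9 ± 3.66 CPM and PAX2 from 1.39 ± 1.24 to 59.5 ± 9.35 CPM. Erythroid genes rose in 6 of 19 and fell in 1 (10 and 1 adjusted over the list alone), median 3.16, or 1.95 at the bounds (adjusted p = 0.0122). SPTB rose from 1.55 ± 0.71 to 80.9 ± 30.9 CPM. Cholesterol synthesis genes rose in 9 of 19 (10 adjusted over the list alone), median 1.31 (adjusted p = 0.0173). Ribosomal protein genes rose in 10 of 67 and fell in 2 (4 and 2 adjusted over the list alone), median 0.38 (adjusted p = 0.0461).

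Interferon response genes fell in 18 of 21 at day 35 (18 adjusted over the list alone), median -3.28 (adjusted p = 8.46e-08). MX1 fell from 318 ± 95.3 to 10.1 ± 5.09 CPM. Genes of the heat shock list fell in 12 of 21 (13 adjusted over the list alone), median -0.65 (adjusted p = 0.00223), with TRIB3 going from 68.4 ± 32.2 to 0.726 ± 0.167 CPM and ATF4 from 1320 ± 238 to 417 ± 30 CPM. Of 14 cartilage and bone genes 6 fell and 1 rose, as many as adjusted over the list alone, median -1.52 (adjusted p = 0.0108). COMP fell from 65.6 ± 25.8 to 5.39 ± 4.27 CPM, and RUNX2, the master regulator of bone, from 108 ± 6.8 to 21.5 ± 6.76 CPM. Of 17 fibroblast matrix genes 8 fell and 2 rose, as many as adjusted over the list alone, median -0.77 (adjusted p = 0.0461), and fibronectin FN1 fell from 8190 ± 1240 to 1840 ± 356 CPM. Apoptosis genes fell in 8 of 16 (8 adjusted over the list alone), median -0.85 (adjusted p = 0.0271). PMAIP1, a BH3-only death factor, fell from 19.3 ± 3.59 to 3.5 ± 1.01 CPM. Of 16 p53 targets 5 fell and 1 rose, as many as adjusted over the list alone, median -0.33 (adjusted p = 0.0461). SESN2 fell from 88.7 ± 13 to 16.3 ± 1.51 CPM. MMP1 fell from 91.9 ± 17.8 to 0.0658 ± 0.114 CPM and FOSL1 from 191 ± 101 to 0.122 ± 0.107 CPM. The p53, ribosomal protein and fibroblast matrix lists lost their calls without normal replicate 1 (adjusted p = 0.0664, 0.0981 and 0.122) and without normal replicate 3 (0.0636, 0.114 and 0.0884). Without NF replicate 1 the p53, ribosomal protein and cartilage lists gave adjusted p of 0.0726, 0.0856 and 0.0668, and with the replicate block the ribosomal protein list gave 0.0639.

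At day 35, 4192 genes passed between normal clones and NF fetuses, 2196 higher and 1996 lower (1787 and 1919 on TPM values, 48.2% higher against 52.4%), with 2186 in all without NF replicate 2 and 1132 with version matching. Calls of the days overlapped in 1133 genes higher at both (307 expected if independent) and 1126 lower at both (305.9 expected), 10 were opposite (615.6 expected), and the correlation across genes was 0.70. The interaction of the comparison with day passed 2 genes (1414 at an unadjusted p under 0.05, and 352 with DESeq2). That count was 42 without day 30 NF replicate 2, 5 without day 35 normal replicate 3, 515 without day 35 abnormal replicate 2, 1 without day 30 NF replicate 1, and 0 without day 30 normal replicate 2, without day 35 normal replicates 1 or 2 and without day 35 NF replicates 1 or 2. It was 56 with the sex covariate, 6 with version matching and 0 on TPM values.

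Abnormal clones were also set against NF fetuses. RNPC3, a protein of the minor spliceosome, was undetected in NF fetuses at day 30 and at least 444-fold higher in abnormal fetuses (96 ± 6.38 CPM, n = 2). DTL, an adaptor for degradation of replication factors, was undetected in abnormal fetuses at day 35 and at least 64.9-fold lower than in NF fetuses (65.4 ± 7.59 CPM, n = 2). Hypoxia and glycolysis genes rose in 17 of 23 at each day (18 and 19 adjusted over the list alone), with medians of 2.29 and 2.42 (adjusted p = 4.03e-07 and 1.44e-06). Interferon response genes fell in 14 and 12 of 21 (17 and 18 adjusted over the list alone), with medians of -2.58 and -2.56, the latter -2.70 at the bounds (adjusted p = 5.99e-05 and 4.4e-07). Ribosomal protein genes rose in 44 and 36 of 67, with 1 lower at day 30 (58 and 52 higher and 1 lower at each day adjusted over the list alone), with medians of 0.85 and 0.76 (adjusted p = 4.17e-09 and 2.16e-10). On TPM values 26 and 6 ribosomal genes were higher, with medians of 0.66 and 0.34, and the day 35 hypoxia list had 8 higher and 1.22. The heat shock list was not called against NF (medians 0.16 and 0.09, adjusted p = 0.929 and 0.155). Camera at the preset correlation called 13 and 11 of 27 lists at the 2 days, and 0 with an estimated correlation (adjusted p at least 0.148 and 0.408). Fibroblast matrix genes had medians of -2.07 and -0.93 (-2.34 and -1.28 on TPM values), cartilage and bone genes -3.11 and -2.47 (-1.91 and -2.22), cardiac genes 3.57 and 1.60 (2.22 and 0.60), kidney genes 2.71 and 1.41 (1.85 and 0.53) and HOX genes 1.60 and 1.19 (1.11 and -0.03). Called at day 30 alone were erythroid (2.97, on TPM values 0.81), liver (4.27, 2.01), neural (1.68, 1.10) and placenta genes (2.01, 1.17), and at day 35 alone paternally expressed (-2.39, -2.72) and cholesterol genes (1.18, 0.63). Endothelial genes rose in 6 of 14 and fell in 1 at day 30 (median 1.32, adjusted p = 0.00522) and fell in 11 of 14 at day 35 (median -2.75, adjusted p = 2.3e-07), a difference that was not tested. At day 30, 2979 genes passed, 1540 higher and 1439 lower (938 and 1893 on TPM values, 33.1% higher against 51.7%, with the median of all genes at -0.23). At day 35, 2301 passed, 1291 higher and 1010 lower (389 and 2085 on TPM values, 15.7% against 56.1%, with the median of all genes at -0.37).

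The abnormal against NF counts moved with single libraries. At day 30 the count was 1265 and 1125 without abnormal replicates 1 and 2, 1263 without NF replicate 2, 4580 without day 35 abnormal replicate 2, 1254 with the sex covariate, which sets aside the same NF library, and 737 with version matching. At day 35 it was 1012 and 4706 without abnormal replicates 1 and 2, 967 and 419 without NF replicates 1 and 2, 1507 with the replicate block, 566 with version matching and 0 with only the compared groups fitted, where the call of DTL ended.

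Among embryos, WT clones were compared with IVF embryos. POU5F1 (chromosome 7, 23564654 to 23570691), the pluripotency factor OCT4, was higher in WT, at 2030 ± 1230 CPM (n = 2) against 27.2 ± 0.209 CPM (n = 2), a log2 fold change of 6.22 ± 1.06 (SE; adjusted p = 0.0124). SOX15 (chromosome 12, 52882840 to 52885785), a SOX factor of early embryos, rose from 6.17 ± 1.44 to 249 ± 105 CPM, and BNIP3, a hypoxia-induced mitophagy receptor, rose from 49.8 ± 16.7 to 1060 ± 445 CPM. The X-linked glycolytic enzyme PGK1 (X chromosome, 62187472 to 62210321) fell from 228 ± 120 to 10.9 ± 0.109 CPM, and the interferon signal transducer STAT2 fell from 69.2 ± 37.1 to 2.55 ± 1.56 CPM. The replication clamp PCNA fell from 322 ± 119 to 41.2 ± 6.12 CPM. CALR, the endoplasmic reticulum chaperone calreticulin, was undetected in IVF and at least 532-fold higher in WT (109 ± 50.2 CPM), and MTG1, a mitochondrial ribosome GTPase, rose from 0.0613 ± 0.0867 to 519 ± 281 CPM.

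Against IVF, 397 of 6960 genes passed, 298 higher and 99 lower in WT. The median of all genes was -0.23, and on TPM values it was -0.51 with 452 higher and 487 lower (48.1% higher against 75.1%), and with DESeq2 796 were higher and 695 lower (53.4%). In the pluripotency list 2 of 15 genes rose (2 higher and 1 lower adjusted over the list alone), with a median of 0.00, or -0.33 at the bounds, and a mean of 0.23 (adjusted p = 0.8). The heat shock list had 2 of 18 genes higher (2 higher and 2 lower adjusted over the list alone) and a median of 0.49, -0.29 on TPM values (adjusted p = 0.57). Camera called 0 of the 20 lists. The count of genes was 36 and 18 without WT replicates 1 and 2, and 2 and 0 without IVF replicates 1 and 2, where each gene named lost its call. BID, PCNA, BNIP3, PGK1 and STAT2 lost theirs without WT replicate 1 as well, and these, POU5F1 and SOX15 without WT replicate 2. The count was 938 without the filter on low counts, 926 with only the compared groups fitted and 90 with version matching, where the call of BID, a death factor that fell from 56.2 ± 6.34 to 6.92 ± 0.919 CPM, ended.

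XIST-KO embryos were compared with WT embryos to ask what loss of XIST changes in clones. PGK1 rose from 10.9 ± 0.109 CPM (n = 2) to 184 ± 134 CPM (n = 2), a log2 fold change of 4.08 ± 0.82 (SE; adjusted p = 0.0428). PSPH, the last enzyme of serine synthesis, rose from 25.9 ± 5.22 to 429 ± 50.4 CPM, GNAS, the stimulatory G protein subunit, from 21.1 ± 2.74 to 347 ± 115 CPM, and BID from 6.92 ± 0.919 to 147 ± 78.5 CPM. SOX15 fell by 22.4 times from 249 ± 105 CPM. LRPAP1 (chromosome 8, 2129492 to 2145632), a chaperone of lipoprotein receptors, fell from 2650 ± 85.8 to 30.9 ± 7.24 CPM, and TEPSIN, a vesicle adaptor, was undetected in XIST-KO and at least 1100-fold lower. Cholesterol synthesis was the list called: 1 of 19 genes rose (1 adjusted over the list alone), median 1.25 (adjusted p = 0.00514, and 0.838 with estimated correlation). That gene, the squalene synthase FDFT1, rose from 44.4 ± 5.65 to 362 ± 211 CPM.

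In total 77 genes passed between XIST-KO and WT, 29 higher and 48 lower, with the median of all genes at 0.15. On TPM values 41 were higher and 194 lower (17.4% higher against 37.7%), and the calls of PGK1 and FDFT1 ended, FDFT1 also with RLE size factors and PGK1, BID and FDFT1 with version matching. The count was 0 without WT replicates 1 or 2 or XIST-KO replicate 2, and 383 without XIST-KO replicate 1. Each gene named lost its call without any of the first 3 of these libraries. On all libraries there were 1320 genes at an unadjusted p under 0.05 and 945 with DESeq2. The other alternatives gave from 21 with version matching to 546 without the filter. The cholesterol median ran from 0.91 to 2.46 with a library left out, and the list gave adjusted p of 0.264 without WT replicate 1 and 0.0605 without XIST-KO replicate 2.

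WT+Kdm4A embryos were compared with WT embryos to ask what added Kdm4A changes in clones. POU5F1 fell from 2030 ± 1230 CPM (n = 2) to 84.6 ± 22.7 CPM (n = 2), a log2 fold change of -4.58 ± 0.98 (SE; adjusted p = 0.0203), and SOX15 fell from 249 ± 105 to 6.39 ± 2.82 CPM. H1FOO, the oocyte linker histone, was undetected with Kdm4A and at least 279-fold lower. BNIP3 fell from 1060 ± 445 to 28 ± 26.6 CPM, and MTG1 fell from 519 ± 281 to 0.11 ± 0.0703 CPM. PGK1 rose from 10.9 ± 0.109 to 143 ± 77.8 CPM, and RPL10, an X-linked ribosomal protein, rose from 2260 ± 421 to 16200 ± 3360 CPM. Camera called 0 of 20 lists. The heat shock list went both ways, with 3 of 18 higher and 2 lower (5 and 3 adjusted over the list alone), a median of -0.08, a mean of 0.07 and an upward test (adjusted p = 1).

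With Kdm4A, 518 genes passed, 205 higher and 313 lower, with the median of all genes at 0.35 (0.23 with RLE size factors and 0.14 on TPM values). On TPM values 220 were higher and 541 lower (28.9% higher against 39.6%), and the call of PGK1 ended. The count was 25 and 314 without WT+Kdm4A replicates 1 and 2 and 35 and 24 without WT replicates 1 and 2, and each gene named except MTG1 lost its call without WT+Kdm4A replicate 1 and without WT replicate 2. Without WT replicate 1 the same calls ended except that of SOX15, and without WT+Kdm4A replicate 2 those of RPL10 and POU5F1. It was 1047 without the filter, 1037 with only the compared groups and 132 with version matching.

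The XIST-KO and WT+Kdm4A comparisons share the same WT libraries. They had 29 genes higher in both (0.9 expected if independent) and 46 lower in both (2.2 expected), with 0 in opposite directions (2.7 expected), and 742 in the same direction with DESeq2. The correlation of fold changes across genes was 0.67 and the covariance 7.24. In 20 simulations with a shared control and no change, the correlation averaged 0.54 (0.52 to 0.57) and the covariance 1.67 (at most 1.87). With at most 1 call in either, 0 shared calls give no baseline. WT was not split, so the shared control or a shift in WT may add to the overlap.

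Other embryo pairs gave few calls. CALR, the tight junction protein IGSF5 and the stress sensor KEAP1 passed in both XIST-KO and WT+Kdm4A against IVF. CALR was at least 539-fold and 549-fold higher and IGSF5 at least 388-fold and 527-fold higher, and KEAP1 rose from 0.0613 ± 0.0867 CPM to 102 ± 16.3 CPM and 101 ± 53.1 CPM (n = 2 per group). Those 3 genes were the whole count in each comparison (1143 and 862 at an unadjusted p under 0.05, 432 and 254 with DESeq2). The XIST-KO count was 1 and 0 without IVF replicates 1 and 2, 40 without XIST-KO replicate 2, 207 without the filter, 9 with the replicate block and 26 on TPM values. The WT+Kdm4A count was 1 and 0 without IVF replicates 1 and 2, 120 without the filter, 13 with the block, 5 with version matching, 15 on TPM values and 0 with only the compared groups. Each of the 3 calls ended without either IVF library. On TPM values the medians of all genes were -0.26 and -0.39, and 4 genes were higher and 22 lower in XIST-KO (15.4% higher against 100%) and 6 higher and 9 lower in WT+Kdm4A (40% against 100%). XIST-KO against WT+Kdm4A passed 0 genes with edgeR (807 at an unadjusted p under 0.05, 207 with DESeq2, 82 without the filter, and 1 and 4 without XIST-KO replicates 1 and 2). Cholesterol synthesis was higher in XIST-KO than in IVF (median 1.00, adjusted p = 0.00122, and 0.918 with estimated correlation) and than in WT+Kdm4A (median 0.92, adjusted p = 0.0179, and 0.892 with estimated correlation). The trophectoderm list was higher in XIST-KO than in WT+Kdm4A (median 1.07, adjusted p = 0.0299, and 0.892 with estimated correlation). The number of lists called against IVF was 1, and 3 without XIST-KO replicate 1, 0 without XIST-KO replicate 2 and 2 without IVF replicate 1. Against WT+Kdm4A it was 2, and 1 without either WT+Kdm4A library and 0 without XIST-KO replicate 2.

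X-linked genes as a set were compared with autosomal genes, since the series is about the active X chromosome. In WT against IVF embryos the median of 275 X-linked genes minus that of autosomal genes was -0.60 (camera p = 0.0431, and 0.278 with estimated correlation), or -0.55 with undetected genes at their bound. In abnormal against normal fetuses the difference was -0.12 at day 30 (p = 0.138), -0.19 at day 35 (p = 0.0375, and 0.506 with estimated correlation) and -0.18 across both days (p = 0.0419, and 0.518 with estimated correlation). In normal clones against NF fetuses it was 0.12 at day 30 (p = 0.358) and 0.28 at day 35 (p = 0.0347, and 0.518 with estimated correlation). It was 0.09 at day 30, where camera at the preset correlation pointed down (p = 0.769), and 0.07 at day 35 (p = 0.689) in abnormal against NF fetuses. With the same correlation it was -0.01 in XIST-KO against WT, where the test pointed up (p = 0.363) and the difference was 0.03 at the bounds, and 0.07 in WT+Kdm4A against WT (p = 0.476). It was -0.29 in XIST-KO against IVF (preset correlation, p = 0.0671), -0.51 in WT+Kdm4A against IVF (p = 0.0504) and -0.02 in XIST-KO against WT+Kdm4A (p = 0.876). These p-values are from camera on all genes of the edgeR model and are not adjusted over the comparisons. The WT against IVF difference was -0.14 without IVF replicate 2 (camera at the preset correlation, p = 0.193), -1.10 without IVF replicate 1 (p = 0.0241), -0.80 without WT replicate 2 (p = 0.0889) and -0.20 with version matching (p = 0.685). With version matching the abnormal against normal difference turned to 0.017 and 0.0025 at day 30 and day 35 (camera at the preset correlation, p = 0.775 and 0.28), and the normal against NF difference was -0.016 and 0.052 (p = 0.574 and 0.461). The day 35 abnormal difference was -0.33 and -0.18 without abnormal replicates 1 and 2 (camera at the preset correlation, p = 0.0815 and 0.155) and -0.09 without normal replicate 2 (p = 0.488). With the same correlation the day 35 normal against NF difference was 0.16 without normal replicate 2 (p = 0.332) and 0.23 without NF replicate 2 (p = 0.0506).

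The X to autosome ratio of median TPM per library was 0.86 ± 0.015 (n = 2) in abnormal, 0.951 ± 0.0196 (n = 3) in normal and 0.807 ± 0.0238 (n = 2) in NF fetuses at day 30. At day 35 it was 0.86 ± 0.077 in abnormal, 1.04 ± 0.161 in normal and 0.871 ± 0.00707 in NF fetuses. Embryos had 1.02 ± 0.197 in WT, 0.94 ± 0.355 in XIST-KO, 1.1 ± 0.0824 in WT+Kdm4A and 1.48 ± 0.435 in IVF (n = 2 each). Abnormal minus normal, averaged over the days, was -0.132 (exact permutation within days, 100 arrangements, p = 0.02), a test chosen after seeing the ratios. It was -0.256 without a filter on TPM (exact p = 0.01) and -0.108 at a mean TPM of at least 5 (exact p = 0.08). With means in place of medians it turned to 0.058 (exact p = 0.38). By day, medians gave -0.091 and -0.174 (exact p = 0.1 and 0.3), with few Y-linked counts in day 35 abnormal fetuses. The embryo ratios were not tested.

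**Figure D3:**
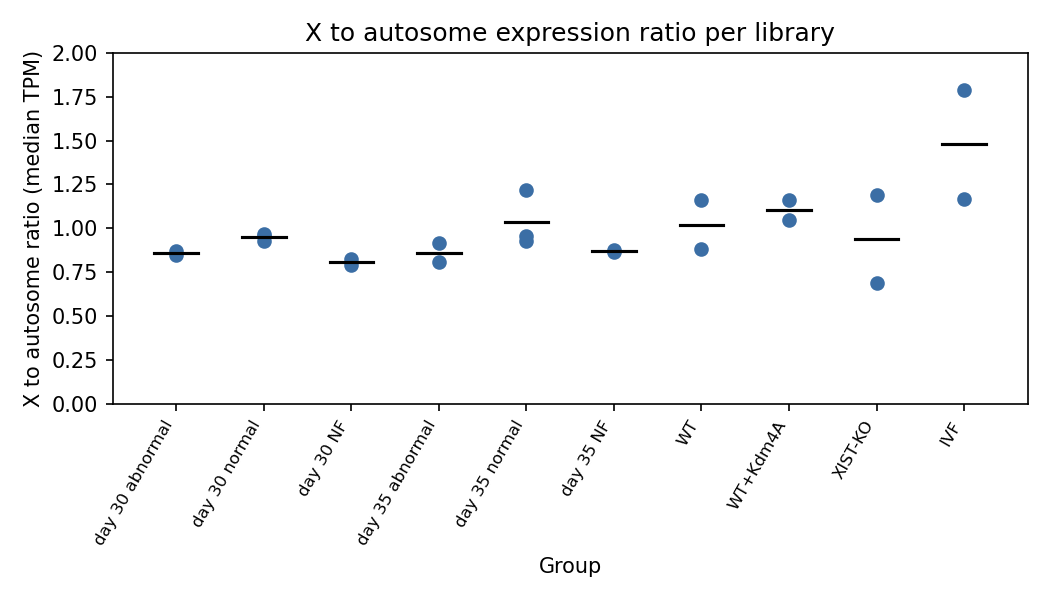
Ratio of the median TPM of X-linked genes to that of autosomal genes, 1 point per library, with the mean of each group as a line. The day 30 abnormal libraries (0.85 and 0.871) lie below the day 30 normal libraries (0.929 to 0.967), but above them with means in place of medians (0.824 and 0.855 against 0.776 to 0.806), and the IVF libraries (1.17 and 1.79) lie far apart.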

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

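Tests of the sex labels, of depth, of mixed RNA, of exchanged libraries and of pooled IVF embryos were chosen only after the result was seen; those of the fibroblast culture list (itself written later than the main results), of detected genes and of other splits of the samples were set before.

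Effects that differed between the days by the interaction test were found for 397 genes in abnormal against normal fetuses and 2 genes in normal against NF fetuses. Fitted day 35 minus day 30 effects for abnormal against normal were 10.38 for DSG3, 8.74 for WDR12, 7.19 for FZD9, 5.10 for ABCB1 and 4.77 for ANXA8. They were -12.60 for GPR20, -12.00 for HNF4A, -10.79 for SOX7, -10.72 for PAX2 and -10.35 for ARHGEF15. Those of genes at 0 in a group depend on the prior count. Further differences were -4.00 for MYL7, -5.47 for HAND1, -4.65 for TAC3, -5.37 for TYROBP, -6.09 for MYBPC1, -3.16 for NEFL, -5.71 for VWF, -5.51 for DLK1, -4.32 for SPTB and -4.13 for C1QB. For normal against NF they were 4.95 for MFAP5 and 2.92 for TNMD.

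Lists that differed between the days in abnormal against normal fetuses had median interactions of 0.50 (X inactivation and Polycomb factors), 0.49 (genes that escape inactivation), -1.90 (paternally expressed) and 0.64 (heat shock and unfolded protein response). The others were -0.34 (ribosomal proteins), -3.0 (leukocyte), -1.85 (neural), -2.32 (skeletal muscle), -3.59 (cardiac), 0.65 (cartilage and bone), -3.62 (endothelium), 0.68 (fibroblast matrix), -0.78 (HOX) and -2.13 (placenta and extraembryonic). In normal against NF fetuses they were -0.48 (X inactivation and Polycomb factors), -0.55 (H3K9 methylation and HP1), 1.02 (cholesterol synthesis), 1.71 (leukocyte), 1.28 (neural), 1.77 (skeletal muscle) and 0.80 (fibroblast matrix), and the X minus autosome difference was 0.19 (camera p = 0.0231, and 0.489 with an estimated correlation). With an estimated correlation 0 of these lists passed, and fry called 9 and 3.

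A record that no table names, outside the genes compared, stood at 1480 CPM in day 30 abnormal replicate 2, 1590 in day 30 NF replicate 1, 2010 in day 35 abnormal replicate 1 and 700 in day 35 abnormal replicate 2, against at most 1.81 in normal fetuses. Of these 4 libraries, 3 hold almost no Y-linked counts. In embryos the record stood at 54.9 and 385 CPM in IVF replicates 1 and 2 and at 0.382 to 15.6 CPM in the cloned libraries.

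Y-linked CPM of day 30 NF replicate 1, labelled male, was 0.0252% of that of replicate 2, labelled female (2 counts; 95% interval 0.00305% to 0.0909%), so exchanged sex labels are a candidate explanation. Low depth is argued against as the reason for few Y-linked counts in day 35 abnormal fetuses, where the lowest normal level predicts 1290 and 177 counts and 12 and 1 were seen. Female RNA mixed into day 30 abnormal replicate 2, at 50.2% of the Y-linked CPM of replicate 1, would need a record level of 2970 CPM in the female source, and that exceeds the 700 to 2010 seen, but the 95% prediction bound from 3 libraries is 4760, which keeps it open. A wrong sex label or a biological loss of Y-linked expression in day 35 abnormal fetuses was not tested.

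Organ markers were low in NF libraries and in both day 35 abnormal libraries. In abnormal replicate 2, 19 of 76 marker genes with at least 10 counts expected had none. Low depth alone is argued against: thinned to it, day 30 normal libraries missed 0.73 to 1.84 (means). Day 35 abnormal replicate 1 missed 19.2 (8 unthinned) and NF 10.9 to 17.5 (1 to 3), so depth adds. An exchange with an NF library is argued against: each NF library was closest to another NF library (Spearman 0.964 to 0.99), and at most 0.905 with a cloned library other than this replicate, which was closest to day 30 NF replicate 1 (0.908). A list of 17 fibroblast culture genes had medians of -2.34 and -2.14 in normal against NF fetuses (camera p = 6.8e-05 and 0.000693, and 0.117 and 0.186 with an estimated correlation), so fibroblast cultures or fibroblast-rich tissue in place of whole body may contribute. Whether clones differ from NF fetuses by cloning or by tissue taken was not tested.

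X-linked expression was lower in WT than in IVF embryos by a difference of -0.60, which ran from -1.10 to -0.14 when a library was left out. The X-linked median of -0.80 lay at percentile 0.12 of 10000 autosomal sets (median -0.22, 95% from -0.54 to 0.01). Sets were matched on expression, not on detection, which leaves fewer detected genes in WT open. Both IVF libraries pool the sexes, so sex and cloning cannot be told apart (other cloned groups: -0.29 and -0.51). Y-linked CPM was 7.35 and 1.88 in WT, 15 and 5.46 in IVF, 0.069 to 5.5 in XIST-KO and 43.8 to 174 in WT+Kdm4A. IVF replicate 2, without which the WT difference was -0.14, held the most of the unnamed record among embryos. Silencing of the active X by XIST in WT clones predicts higher X-linked expression in XIST-KO than in WT, where the difference was -0.01 (camera at the preset correlation, p = 0.363) and 0.00 to 0.24 when a library was left out, but that span includes the size of the WT against IVF difference without IVF replicate 2, which keeps silencing open.

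Cloned fetus libraries were split otherwise within days. Over both days, only the real split of 100 reached 3073 changed genes (others at most 457), so chance is unlikely. Few Y-linked counts at day 35 go with the label. For lists, 65 of 100 reached the real 9 (others: median 10, at most 16), so chance stays open.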

How the results depend on the processing

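Matching of records with their version, omission of day 35 abnormal replicate 2 from fits of other groups, and the overlap of normal against NF calls under other settings were chosen after seeing the data. The other alternatives were planned. Of 1015 results of named genes under alternatives other than leaving out a library, 990 kept their direction and side of the threshold and 25 lost their call. Of 643 leaving out a library, 545 kept both, 94 lost their call and 4 reversed. The named genes were chosen among those the selection rule gave partly for keeping their calls, so these counts do not describe other genes. For called lists, 180 of 248 alternatives kept the call and 68 lost it, 60 of them with an estimated correlation, 6 with fry and 2 with the replicate block. Leaving out a library kept 323 of 354, ended 30 and reversed 1. Where an omission leaves a group with 1 library, that library is assumed to vary like the other groups. Same-number libraries correlated at -0.07 to 0.15 in fetuses and -0.31 to 0.09 in embryos after group means were removed, so the numbers were not used as pairs, and the block is an alternative. XIST gave no value under any alternative, since no record matched it. Simulated changes of log2 3 were recovered in 93% of genes in fetuses and 16% in embryos, and of log2 1 in 22.2% and 0%. Depth was not separated from spread or group: WT and IVF lay below XIST-KO and WT+Kdm4A, and abnormal below normal fetuses. Causes were not tested unless given.

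Counts of changed genes with the replicate block were 734 and 1498 in abnormal against normal fetuses at day 30 and day 35, 1507 in abnormal against NF at day 35 and 1976 across both days. With the block they were also 155 for the abnormal by day interaction, 141 in XIST-KO against WT, 9 in XIST-KO against IVF and 13 in WT+Kdm4A against IVF. With records matched by version, where fewer genes were tested, they were 375 and 609 in abnormal against normal, 731 and 1132 in normal against NF and 737 and 566 in abnormal against NF. Matching by version also gave 826 across both days, 115 and 6 for the interactions of abnormal and of normal fetuses, 90 in WT against IVF, 21 in XIST-KO and 132 in WT+Kdm4A against WT and 5 in WT+Kdm4A against IVF. With only the compared groups fitted they were 3906 and 297 in abnormal against normal, and 0 in abnormal against NF at day 35. In embryos fitted this way they were 926 in WT against IVF, 293 in XIST-KO and 1037 in WT+Kdm4A against WT and 0 in WT+Kdm4A against IVF. The covariate of labelled sex, which sets aside the single library labelled female, gave 1295 in normal and 1254 in abnormal against NF at day 30 and 56 for the normal interaction. On TPM values the interactions gave 696 and 0, WT against IVF 939, XIST-KO against WT 235, and XIST-KO and WT+Kdm4A against IVF 26 and 15. Without the filter the counts were 938 in WT against IVF, 546 and 1047 in XIST-KO and WT+Kdm4A against WT, and 207 and 120 against IVF. They were 82 in XIST-KO against WT+Kdm4A and 451 in the overlap of the comparisons with WT. DESeq2 gave 942 and 352 for the interactions, 1491 in WT against IVF, 945 and 1567 against WT and 432 and 254 against IVF. It gave 207 in XIST-KO against WT+Kdm4A and 742 in the overlap.

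Lists called with an estimated correlation numbered 0 and 1 in abnormal against normal at day 30 and day 35, 0 and 0 in normal against NF, and 0 and 0 in abnormal against NF. They numbered 1 across both days, 0 and 0 for the interactions, and 0, 0 and 0 in XIST-KO against WT, IVF and WT+Kdm4A. Fry called 16 across both days, 9 and 3 for the interactions, and 0, 0 and 0 in the same XIST-KO comparisons.

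The X minus autosome difference with records matched by version was 0.017 and 0.0025 in abnormal against normal at day 30 and day 35, -0.016 and 0.052 in normal against NF, and -0.034 in abnormal against NF at day 35. In embryos it was -0.20 in WT against IVF and 0.17 in XIST-KO against WT. In WT against IVF it was -0.50 with the replicate block, -0.61 with only the compared groups, -0.25 on TPM values, -0.76 without the filter and -0.60 (p = 0.278) with an estimated correlation. At day 35 it was -0.17 on TPM values and -0.19 (p = 0.506) with an estimated correlation in abnormal against normal, and 0.25 without the filter and 0.28 (p = 0.518) with an estimated correlation in normal against NF. In XIST-KO against WT it was 0.042 with the block, 0.014 with only the compared groups, 0.095 with the stricter filter, 0.055 without the first 7 Mb of X and 0.19 at an average log2 CPM of at least 3. In WT+Kdm4A against IVF it was -0.51 (camera at the preset correlation, p = 0.0444) with only the compared groups and -0.52 (p = 0.0468) without the first 7 Mb. The X to autosome ratio without a filter on TPM was 0.744 and 0.684 in abnormal fetuses at day 30 and day 35, and 0.765 in day 35 NF. In embryos it was 0.459 in WT+Kdm4A, 0.419 in WT, 0.436 in XIST-KO and 0.918 in IVF. At a mean TPM of at least 5 it was 0.886 in day 30 abnormal, 0.806 in day 35 NF, 1.2 in WT+Kdm4A and 1.31 in XIST-KO. With means in place of medians abnormal lay above normal, at 0.84 and 0.794 at day 30 and 1.03 and 0.955 at day 35, and the ratio was 0.833 in day 35 NF, 0.452 in WT and 0.985 in IVF.

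Leaving out a library gave 423 to 3187 and 1418 to 3645 changed genes in abnormal against normal at day 30 and day 35, and 1287 to 4453 and 2186 to 5605 in normal against NF. It gave 1125 to 4580 and 419 to 4706 in abnormal against NF and 113 to 2892 and 0 to 515 for the interactions. In embryos it gave 0 to 36 in WT against IVF, 0 to 383 and 24 to 314 in XIST-KO and WT+Kdm4A against WT, 0 to 40 and 0 to 3 against IVF and 0 to 4 in XIST-KO against WT+Kdm4A. Lists called ranged from 7 to 12 in abnormal against normal at day 35, 0 to 1 in XIST-KO against WT, 0 to 3 against IVF and 0 to 3 against WT+Kdm4A. X differences ranged from -0.33 to -0.093 in abnormal against normal and 0.16 to 0.36 in normal against NF at day 35, -1.10 to -0.14 in WT against IVF and 0.00 to 0.24 in XIST-KO against WT. They ranged from -0.73 to -0.10 and -0.64 to -0.20 in XIST-KO and WT+Kdm4A against IVF and -0.26 to 0.20 between them. At day 30 AFP ranged from -0.40 to 8.67 and AHSG from -2.60 to 8.54. At day 35 HBE1 ranged from -9.23 to 6.43, HBZ from -8.79 to 6.25 and the ribosomal protein list from -0.092 to 0.73.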

Other observations

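None of the 5 tests here was chosen after its own result was seen, though their lists were written after the main results. Amino acid starvation genes, targets of the transcription factor ATF4, were higher in abnormal than in normal fetuses: 11 of 12 rose at day 35 (median log2 fold change 1.85, camera p = 4.15e-13, and 0.0107 with an estimated correlation) and 3 of 12 at day 30 (0.48, p = 0.0362, and 0.354 with an estimated correlation). The day difference had a median of 1.61 (interaction p = 1.15e-07, and 0.0405 with an estimated correlation). In normal against NF fetuses 6 of 12 fell at day 30 (-0.89, p = 0.00706, and 0.246 with an estimated correlation) and 8 of 12 at day 35 (-1.66, p = 3.79e-05, and 0.0931 with an estimated correlation). In abnormal against NF fetuses the list was not called, with 2 higher and 4 lower at day 30 (-0.15, p = 0.368, and 0.687 with an estimated correlation) and 2 higher at day 35 (0.66, p = 0.0715, and 0.424 with an estimated correlation).

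An amino acid starvation response was proposed for the stress genes of abnormal fetuses. Its condition, a median above 0 with camera p under 0.05, was met at both days (0.48 and 1.85), at day 30 not with an estimated correlation. The response may be part of the stress pattern at day 35 against normal fetuses. Fibroblast culture genes moved the same way in these comparisons (medians 1.66 and 2.43 in abnormal against normal, -2.34 and -2.14 in normal against NF), so a change of cell types stays open and was not tested.

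Higher glycolysis genes could go with lower oxidative phosphorylation genes. The 62 genes of that list had medians of -0.10 at day 30 (camera at the preset correlation, p = 0.737) and 0.01 at day 35 (p = 0.911), with 1 higher at day 30 and 2 higher and 4 lower at day 35. The day 35 median met the bound written against the explanation by 0.01 alone and the mean was -0.17, so both days stay open.

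Higher cholesterol genes in XIST-KO than in WT embryos could be part of a wider rise of lipid synthesis. The 9 fatty acid synthesis genes had a median of 1.14, a mean of 0.28 and 0 called genes by edgeR (camera at the preset correlation, p = 0.262), which leaves the explanation open.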
